A study of Mus musculus with 18 samples.

How the data were processed

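Stool of 18 mice, 6 susceptible and 12 resistant to oral anaphylaxis, was analysed as a table of 16S rRNA gene counts. Per the labels' protocols, the authors extracted DNA from stool pellets, amplified the V1 to V3 region of the gene with a high-fidelity polymerase, pooled the amplicons and sequenced them in paired reads on a MiSeq instrument. The deposited values are whole-number counts per sequence feature and mouse, with no normalization seen in the values, and a deposited second table gives the authors' taxonomic names of each feature. How reads were trimmed, joined or denoised, and which classifier, reference database and filters were used, is not given in the sources used here. Such steps can change the number of rare features and the names, so richness and names hold for this table alone. Features are written by their lowest named rank, followed by F- and the first characters of the deposited identifier.

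Groups were taken from the labels, which give the response to oral anaphylaxis of each mouse, and mice were numbered within their group in accession order. The labels used give no cage, litter, sex, collection day or sequencing batch, so none entered a test. All 81 pairs of libraries within a group differed in a chi-square test of their counts (lowest chi-square per degree of freedom 17.3). No pair thus agreed within counting noise, and each library counted as 1 mouse, as labelled. The test covers counting error only and takes reads as independent. Totals ran from 673 to 3905 counts per mouse. A share in a single mouse therefore rests on steps of 0.0256% to 0.149% per count. Floors for a count of 0 are 3 counts over the total and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Of the 419 features, 244 were found in 1 mouse and held 5.52% of counts, and 3 were found in all 18 mice. Features with no genus name, 89 in number with 9.75% of counts, were summed under the lowest named rank. The table then held 51 genera, 28 families and 8 phyla, with 2 features that have no phylum name.

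Features, genera and families with 10 or more counts and found in at least 4 mice were tested between the groups with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are susceptible over resistant, and their standard errors were computed from the fold change and the F statistic. The Shannon index (natural log), richness rarefied to 673 counts by the hypergeometric formula, the log2 ratio of Firmicutes to Bacteroidota, log2 library totals, distance to the group centroid (recomputed in every split) and the log2 percent (plus 0.01) of 22 taxon groups were compared with two-sided exact permutation tests over all 18564 splits of the mice into 6 and 12, whose smallest possible p is 5.39e-05. Intervals at 95% for these differences come from inverting the permutation test. Permutational multivariate analysis of variance (PERMANOVA) on Bray-Curtis dissimilarity of relative abundances used the same splits. Presence was tested with Fisher's exact test for features found in 4 to 14 mice. Member features of the taxon groups were tested with edgeR and with fry. Relations with the sample number used 100000 permutations. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these tests.

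The taxa named in the text follow a rule set before the data were examined: per level, those past the threshold, at most 10 per direction; where fewer than 10 passed among features or genera, those with the smallest unadjusted p up to 10, described as not past the threshold; the 6 families and 6 genera with the highest mean relative abundance; and every taxon group found. Other taxa named, such as Muribaculaceae F-ab7f13, Saccharimonadaceae, Acholeplasmataceae and the family Clostridia_vadinBB60_group, were chosen after their values were seen. Taxon groups were matched by whole names at any rank, so genera written with a bracketed Eubacterium were not counted among the butyrate-producing genera.

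Alternatives set before the data were examined were DESeq2 size factors and library totals in place of TMM, the DESeq2 Wald test (DESeq2 1.42.0), limma on centred log-ratios of counts plus 0.5, no filter, a filter of 9 mice, a robust fit, other diversity indices, distances and taxonomic levels, other pseudocounts, and leaving out each mouse in turn. Alternatives chosen after seeing the data were a filter of 2 mice, leaving out the 2 libraries under 1500 counts, presence per genus and the number in the sample title as a covariate. The count tests were checked on simulated data with the real means, library sizes and fitted dispersion: at a 16-fold change edgeR recovered 2.5% of changed features among 83, 31.7% of changed genera among 26 and 42.5% of changed families among 16, and at a dispersion of 0.1 it recovered 98.8%, 100% and 97.5%. The mouse reference genome was not used here, since the counts are of bacterial sequence.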

Results

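The stool bacteria of 18 peanut-sensitized mice were profiled by sequencing of the 16S rRNA gene, which identifies bacteria by the sequence of a conserved gene. The mice were second-generation (N2) hybrids of the C57BL/6 and C3H/HeJ inbred strains, and stool was taken after 6 weeks of sensitization to peanut. Of these, 6 mice were susceptible to oral anaphylaxis, the acute allergic reaction to swallowed allergen, and 12 were resistant. The comparison of the 2 groups asks whether the stool bacteria of susceptible mice differed from those of resistant mice of the same hybrid generation and weeks of sensitization. The table held 43267 counts over 419 sequence features, with 673 counts in resistant mouse 3, 3905 in susceptible mouse 6 and a median of 2534.5 per mouse. Library totals averaged 2378 ± 860 counts (SD, n = 6) in susceptible and 2416 ± 915 (SD, n = 12) in resistant mice (difference on the log2 scale 0.04, two-sided exact permutation p = 0.903).

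Stool of both groups was dominated by Lachnospiraceae, a Clostridia family with many short-chain fatty acid producers, and Muribaculaceae, a carbohydrate-degrading Bacteroidales family abundant in mouse stool. Lachnospiraceae made up 53.3 ± 24.4% of counts (SD, n = 6) in susceptible and 44.7 ± 20.6% (SD, n = 12) in resistant mice. Muribaculaceae made up 29.2 ± 18.7% (SD, n = 6) and 32.9 ± 23.0% (SD, n = 12). Lactobacillaceae, lactic acid bacteria represented here by Lactobacillus, averaged 6.73 ± 7.07% (SD, n = 6) in susceptible and 10.6 ± 8.12% (SD, n = 12) in resistant mice, and Rikenellaceae averaged 5.49 ± 4.76% (SD, n = 6) and 8.71 ± 7.26% (SD, n = 12). Bacteroidaceae, all of it the glycan-degrading genus Bacteroides, was found in 4 of 6 susceptible and 4 of 12 resistant mice, and Oscillospiraceae in 5 of 6 and 9 of 12. The families outside these 6 summed to 2.19 ± 1.04% (SD, n = 6) and 1.26 ± 0.975% (SD, n = 12). Mice differed widely: Lachnospiraceae ran from 10.9% to 87.3% of a mouse's counts and Muribaculaceae from 0.844% to 69.3%.

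**Figure D1:**
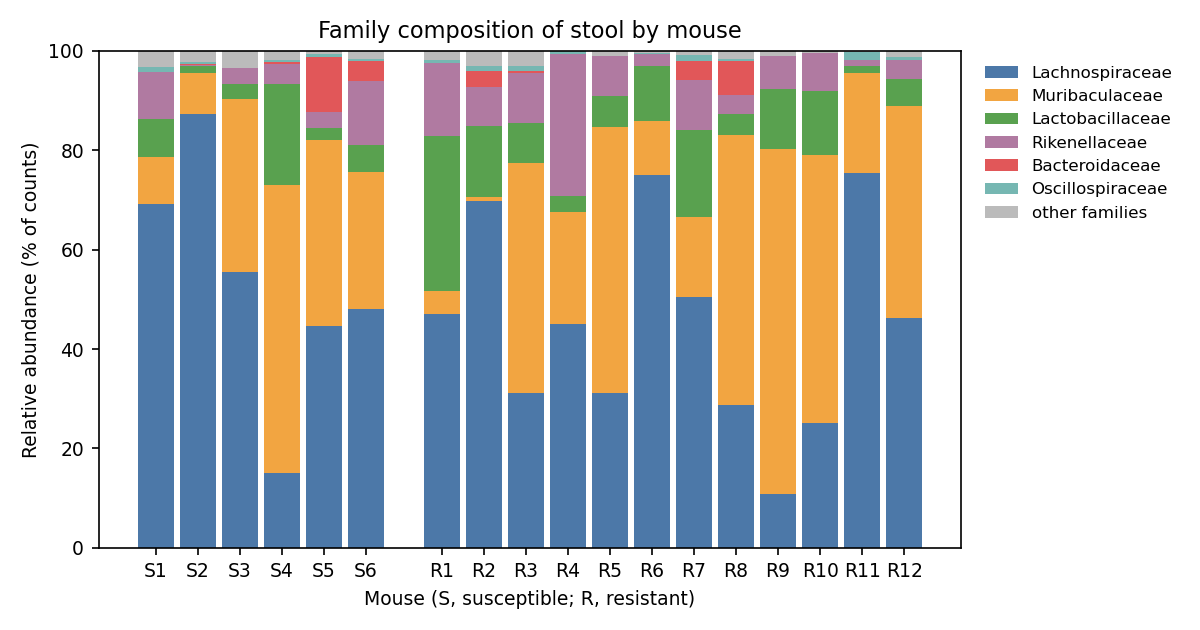
Relative abundance of the 6 most abundant families in percent of counts, 1 stacked bar per mouse, for the 6 susceptible (S) and 12 resistant (R) mice. Lachnospiraceae (blue) ranged from 10.9% to 87.3% and Muribaculaceae (orange) from 0.844% to 69.3% of counts in a mouse.

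At the phylum level Firmicutes, which holds Lachnospiraceae and Lactobacillaceae, made up 61.7 ± 19.8% of counts (SD, n = 6) in susceptible and 56.5 ± 22.7% (SD, n = 12) in resistant mice. Bacteroidota, which holds Muribaculaceae and Rikenellaceae, made up 37.6 ± 20.3% (SD, n = 6) and 43.3 ± 22.9% (SD, n = 12). The log2 ratio of Firmicutes to Bacteroidota was 0.39 higher in susceptible mice, with a 95% interval from -1.25 to 2.04 (two-sided exact permutation p = 0.613), and the difference was -0.0858 without susceptible mouse 2. Patescibacteria, represented only by Candidatus_Saccharimonas, averaged 0.521 ± 0.595% (SD, n = 6) and 0.0817 ± 0.125% (SD, n = 12). This phylum was examined after its values were seen, and over the 9 phylum-level categories its difference missed the threshold (exact permutation p = 0.0154, adjusted p = 0.138). Desulfobacterota, a phylum of sulfate reducers, was found in 2 susceptible mice and in 0 of 12 resistant mice.

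Diversity within a mouse did not pass the test between the groups. The Shannon index, which rises with the number and evenness of features, was 3.49 ± 0.292 (SD, n = 6) in susceptible and 3.40 ± 0.257 (SD, n = 12) in resistant mice. The difference of 0.091 had a 95% interval from -0.196 to 0.374 (two-sided exact permutation p = 0.501), and was 0.0313 without susceptible mouse 6 and 0.191 without susceptible mouse 2. Rarefied richness, the number of features expected in 673 counts, was 54.6 ± 10.6 (SD, n = 6) and 52.8 ± 12.5 (SD, n = 12). Its difference of 1.76 features had a 95% interval from -11.0 to 14.5 (two-sided exact permutation p = 0.770) and turned to -2.71 without the 2 libraries under 1500 counts, an alternative added after the data were seen. Rarefied genus richness was 16.8 ± 2.67 (SD, n = 6) and 13.4 ± 3.76 (SD, n = 12), a difference of 3.39 genera with a 95% interval from -0.286 to 7.03 (two-sided exact permutation p = 0.0673). The difference in feature richness was also negative, down to -1.84, when resistant mouse 3 or susceptible mouse 6 was left out.

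**Figure D2:**
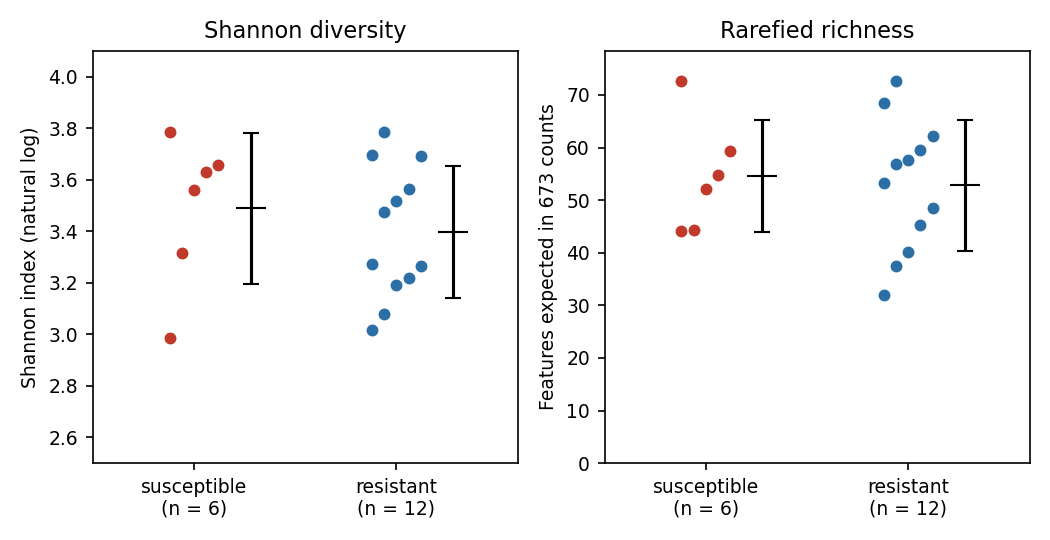
Shannon index (natural log, axis starting above 0) and rarefied richness (features expected in 673 counts) for each mouse, with the mean and SD of each group beside the points. The groups overlap across their range, with mean Shannon indices of 3.49 and 3.40 and mean rarefied richness of 54.6 and 52.8.

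Feature-level diversity followed the number in the sample titles, whose meaning the labels do not give, and genus-level richness did not. Across the 18 mice, rarefied richness correlated with that number with a Pearson r of 0.820 (permutation p = 6e-05, adjusted p = 0.00036) and a Spearman rho of 0.851 (permutation p = 2e-05, adjusted p = 0.00012), the adjustment covering the 6 measures examined. Without the 2 mice farthest from the median number, r was 0.837 (permutation p = 5e-05). Within the 12 resistant mice rho was 0.825 (permutation p = 0.00158), and within the 6 susceptible mice 0.943 (exact permutation p = 0.0167). The mean number was 41.7 in susceptible and 41.4 in resistant mice, and with the number as a covariate the group difference in richness was 1.31 features (permutation p = 0.721). Rarefied genus richness had a Pearson r of -0.0508 (permutation p = 0.841) and a Spearman rho of -0.0588 (permutation p = 0.818) with the number. The relation was noticed in the data and then tested.

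**Figure D3:**
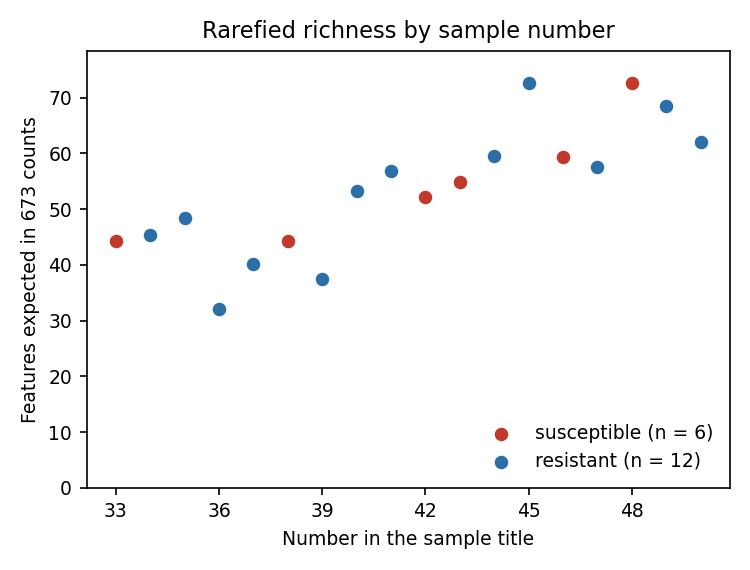
Rarefied richness (features expected in 673 counts) of each mouse against the number in its sample title, coloured by group. Mice with higher numbers had more features (Spearman rho 0.851), in resistant mice (0.825) and in susceptible mice (0.943).

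Composition as a whole did not pass the test between the groups. Feature-level Bray-Curtis dissimilarity, the share of the community not held in common, averaged 0.701 between susceptible mice, 0.658 between resistant mice and 0.697 between mice of different groups. In a permutational multivariate analysis of variance, a permutation test of composition, the group explained 8.35% of the variation (pseudo-F = 1.46, exact p = 0.135 over all 18564 splits of the mice). The median split explained 5.46% and the 95th percentile of splits 10.1%. With single mice left out, the exact p of this test ran from 0.0543 to 0.245. With the sample number as a covariate, an alternative added after the data were seen, its permutation p was 0.0676. Distance to the own group's centroid was 0.456 ± 0.0514 (SD, n = 6) in susceptible and 0.448 ± 0.0568 (SD, n = 12) in resistant mice (two-sided exact permutation p = 0.852 with the centroids recomputed in every split, 0.797 with each mouse's distance held fixed). In simulations, the mice were shuffled and 20 features were changed. There the permutation test of composition detected a 4-fold change in 22 of 40 runs and a 16-fold change in 40 of 40.

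**Figure D4:**
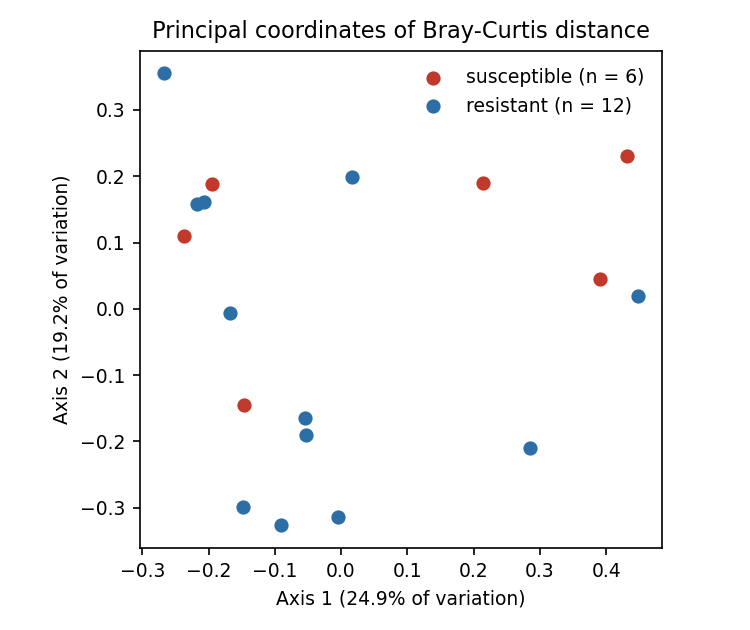
Principal coordinates of the Bray-Curtis dissimilarity between mice, 1 point per mouse, coloured by group. Axes 1 and 2 hold 24.9% and 19.2% of the variation, and points of both groups lie among each other.

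No family passed the planned test between the groups, and the taxa closest to the threshold were families of low abundance. Clostridia_vadinBB60_group, an uncultured Clostridia lineage, made up 0.286 ± 0.253% of counts (SD, n = 6) in susceptible mice, where it was found in 4 of 6, and 0.0350 ± 0.121% (SD, n = 12) in resistant mice, where it was found in 1 of 12 (adjusted p = 0.101, edgeR). With the sample number as a covariate, an alternative added after the data were seen, edgeR called this 1 family (adjusted p = 0.00382; the lowest adjusted p of any family ran from 0.00286 to 0.676 over the alternatives). Saccharimonadaceae, the family of Candidatus_Saccharimonas, had the same adjusted p of 0.101 and was found in 4 of 6 and 4 of 12 mice. Lachnospiraceae had a log2 fold change of 1.39 ± 0.63 (SE) with an adjusted p of 0.195 (edgeR). Rikenellaceae had -0.43 ± 0.57 and an adjusted p of 0.662, Lactobacillaceae -0.12 ± 0.56 and 0.881, Muribaculaceae 0.21 ± 0.68 and 0.866, Bacteroidaceae 1.74 ± 1.57 and 0.623, and Oscillospiraceae 0.10 ± 1.20 and 0.933. Of 16 families tested, edgeR called 0 at an adjusted p of 0.05 (3 at an unadjusted p under 0.05), DESeq2 called 0 (0 unadjusted) and limma on centred log-ratios called 0 (1 unadjusted). TMM scaling shifted the family fold changes together: their median was 1.43 with TMM, 0.18 with library totals alone and -0.06 with DESeq2 size factors, so that Lachnospiraceae lay at the median and took a value of -0.32 with DESeq2 size factors. Calls of 1 family appeared when single mice were left out: Clostridia_vadinBB60_group without resistant mouse 1 or susceptible mouse 6, and Lachnospiraceae without susceptible mouse 4 or resistant mouse 12. Resistant mouse 1 was the only resistant mouse in which Clostridia_vadinBB60_group was found. Such lone calls carry little weight, since the planned edgeR test called at least 1 family in 18 of 100 drawn splits of the mice.

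Among genera, the lowest p-values belonged to Clostridia taxa with higher mean abundance in susceptible mice. Clostridia_vadinBB60_group had a log2 fold change of 3.74 ± 1.55 (SE) and [Eubacterium]_xylanophilum_group, a Lachnospiraceae genus named after a xylan degrader, 3.57 ± 1.62 (SE), both with an adjusted p of 0.366 (edgeR). With the sample number as a covariate, Clostridia_vadinBB60_group was the 1 genus called (adjusted p = 0.0278, edgeR). Its adjusted p ran from 0.0278 to 0.891 over the alternatives on all 18 mice. With single mice left out it ran from 0.00328 to 0.971 (edgeR). Candidatus_Saccharimonas had 2.91 ± 1.59, Alistipes, a Rikenellaceae genus, 2.74 ± 1.65, and the unnamed genera of Erysipelotrichaceae 2.69 ± 1.58, all with an adjusted p of 0.382 (edgeR). Unnamed genera of Lachnospiraceae made up 11.3 ± 6.29% of counts (SD, n = 6) in susceptible and 6.31 ± 4.92% (SD, n = 12) in resistant mice, with a log2 fold change of 1.35 ± 0.78 that was 0.46 with DESeq2 size factors. [Eubacterium]_coprostanoligenes_group had 2.38 ± 1.45, Bacteroides 1.73 ± 1.21 and GCA-900066575, a genus known by a genome identifier, 1.75 ± 1.55. Among the abundant genera, Lachnospiraceae_NK4A136_group made up 31.4 ± 23.2% (SD, n = 6) and 22.6 ± 13.1% (SD, n = 12), and its log2 fold change of 0.76 turned to -0.20 with DESeq2 size factors. The genus-level group Muribaculaceae averaged 28.7% and 32.0%, Lachnospiraceae_UCG-001 7.38% and 12.9%, Lactobacillus 6.73% and 10.6%, and Rikenellaceae_RC9_gut_group 5.14% and 8.64%, all with an adjusted p of 0.942 (edgeR). Of 26 genera tested, edgeR called 0 (2 at an unadjusted p under 0.05), DESeq2 called 0 (0 unadjusted) and limma on centred log-ratios called 1 (2 unadjusted). The limma call was [Eubacterium]_xylanophilum_group (adjusted p = 0.0054). For this genus the adjusted p ran from 0.0054 to 0.891 over the alternatives on all 18 mice. With single mice left out it ran from 0.216 to 0.971 (edgeR). The median log2 fold change of genera was 0.67 with TMM, 0.26 with library totals alone and -0.27 with DESeq2 size factors, and the values of all 14 named genera were lower with DESeq2 size factors than with TMM, at 2.05 for Clostridia_vadinBB60_group, 2.09 for [Eubacterium]_xylanophilum_group, 1.66 for Candidatus_Saccharimonas and 0.60 for Bacteroides. Leaving out resistant mouse 1 gave a call of Clostridia_vadinBB60_group (log2 fold change 6.19). Leaving out resistant mouse 3 gave a call of Alistipes (5.44). Resistant mouse 1 held all 14 counts of Clostridia_vadinBB60_group in resistant mice, so 6.19 was fitted against no counts there. Resistant mouse 3 held 4 of the 6 counts of Alistipes in resistant mice. At least 1 genus was called by the planned edgeR test in 14 of 100 drawn splits of the mice.

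[Eubacterium]_xylanophilum_group was found in 6 of 6 susceptible and 2 of 12 resistant mice. It made up 0.903 ± 0.588% of counts (SD, n = 6) in susceptible mice, with 0.282% in the lowest of them, and 0.137 ± 0.326% (SD, n = 12) in resistant mice. The genus summed 2 features. F-b3e8c8 was found in 5 susceptible and 2 resistant mice (Fisher's exact p = 0.0128, adjusted p = 0.608 over the features tested). F-19eac7 was found with 11 counts in susceptible mouse 6 only, the mouse with the lowest share. Fisher's exact test of presence, run over 20 genera after the data were seen, gave this genus p = 0.00151 (two-sided exact, adjusted p = 0.0302). Clostridia_vadinBB60_group followed with 4 of 6 against 1 of 12 mice (exact p = 0.0217, adjusted p = 0.217). With any 1 susceptible mouse left out, presence of [Eubacterium]_xylanophilum_group was 5 of 5 against 2 of 12, and the smaller group no longer reached the threshold (adjusted p from 0.0577 to 0.0679, Fisher's exact test). Without the 2 libraries under 1500 counts it was 6 of 6 against 2 of 10 (exact, adjusted p = 0.126). In the planned edgeR test on all 18 mice, the adjusted p of its abundance was 0.366. Presence of single features, tested for 84 features as planned, gave 0 calls (3 at an unadjusted p under 0.05, Fisher's exact test), with a lowest adjusted p of 0.608.

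**Figure D5:**
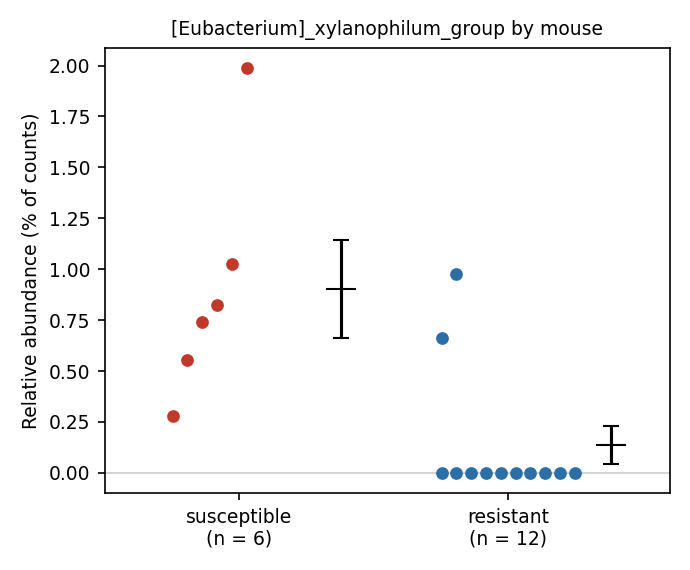
Relative abundance of [Eubacterium]_xylanophilum_group in percent of counts for each mouse, with the mean and standard error of each group beside the points. All 6 susceptible mice lie above 0 and 10 of 12 resistant mice lie at 0.

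Of single features, the lowest p-value belonged to Lachnospiraceae F-0e3d51, which was not past the threshold. This feature of an unnamed genus was found in 0 of 6 susceptible mice and in 5 of 12 resistant mice with 146 counts (adjusted p = 0.807, edgeR). Taking 3 counts over the group as the floor, its share of the pooled counts was at least 23.9-fold lower in susceptible mice. That bound covers counting error only, not the spread between mice. The other 9 features named by rank of p all had an adjusted p of 0.964 (edgeR). Higher on average in susceptible mice were Lachnospiraceae_NK4A136_group F-0d3510 (5.03% against 1.06% of counts) and F-5d432e (4.78% against 1.38%), Candidatus_Saccharimonas F-04c584 (0.521% against 0.0478%), Clostridia_vadinBB60_group F-f40f1a (0.242% against 0.0350%) and Lachnospiraceae F-a97557 (0.424% against 0.0643%). Higher on average in resistant mice were Lachnospiraceae_NK4A136_group F-5250d8 (5.77% against 1.82%) and Muribaculaceae F-df20a7 (0.211% against 0.0258%), F-bfad3d (0.0725% against 0.00427%) and F-38b028 (0.0347% against 0.00427%). Lachnospiraceae_NK4A136_group thus held features with means in opposite directions. Of 83 features tested, edgeR called 0 at an adjusted p of 0.05 (1 at an unadjusted p under 0.05), DESeq2 called 0 (1 unadjusted) and limma on centred log-ratios called 0 (4 unadjusted). This count depended on the filter: edgeR called 64 of 419 features without one, 52 of them found in 1 mouse, and 10 with a filter of 2 mice. Of 100 splits of the mice, the real one included, 12 gave at least 64 calls without a filter. Without resistant mouse 7, edgeR called 1 feature, Muribaculaceae F-ab7f13. That mouse was the only resistant carrier of the feature, at 10.6% of its counts, against 4 susceptible carriers. At least 1 feature was called by the planned edgeR test in 9 of 100 drawn splits of the mice. At the spread between mice seen here, the test had little reach for single features. In simulations with the fitted dispersion, edgeR recovered 2.5% of features and 31.7% of genera changed 16-fold. At a dispersion of 0.1 with the same group sizes it recovered 98.8% and 100%.

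None of the taxon groups chosen before the data were examined passed the test between susceptible and resistant mice. Of 22 groups, 14 were found, and 0 passed an exact permutation test on log2 percent (0 at an unadjusted p under 0.05, lowest adjusted p 0.956). Clostridia, the class that holds Lachnospiraceae, made up 54.4 ± 24.4% of counts (SD, n = 6) in susceptible and 45.6 ± 21.1% (SD, n = 12) in resistant mice. For Lachnospiraceae the log2 difference was 0.25 with a 95% interval from -0.62 to 1.11, for Muribaculaceae 0.17 with an interval from -1.55 to 1.94, which turns negative on the percent scale, for Lactobacillaceae -0.82 with an interval from -2.13 to 0.51, and for Rikenellaceae -0.97 with an interval from -2.57 to 0.58. Ruminococcaceae and Oscillospiraceae, Clostridia families with many fibre degraders, together averaged 0.637 ± 0.249% (SD, n = 6) and 0.698 ± 0.620% (SD, n = 12). Bacteroides and Parabacteroides averaged 2.61 ± 4.44% (SD, n = 6) and 1.19 ± 2.25% (SD, n = 12), and Erysipelotrichales 0.369 ± 0.475% and 0.186 ± 0.286%. The butyrate-producing genera of the list averaged 0.0494 ± 0.121% and 0.716 ± 2.31%, with 243 of their 265 counts from Roseburia in 1 resistant mouse. Prevotellaceae, found in 1 of 6 and 3 of 12 mice, and Deferribacteraceae, which live in the mucus layer and were found in 1 mouse of each group, were sparse. Desulfovibrionaceae, the sulfate reducers, were found in 2 of 6 and 0 of 12 mice with 13 counts (exact permutation p = 0.0980, adjusted p = 0.956), Proteobacteria in 3 mice with 9 counts, and Actinobacteria in 1 resistant mouse with 2 counts.

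At the level of member features, 0 rose and 0 fell in the 7 groups with features that could be tested, adjusted over the list alone or over all features tested (edgeR). The other 7 groups found had no feature past the count filter. Of 34 Muribaculaceae features tested, 13 had a higher estimate in susceptible mice, as did 16 of 33 Lachnospiraceae, 1 of 7 Lactobacillaceae and 1 of 3 Rikenellaceae features. The rotation test fry, which asks whether a set's members move on balance one way, gave its lowest adjusted p, 0.912, for Lactobacillaceae and Rikenellaceae. The 8 groups with 0 counts were Bifidobacteriaceae, Akkermansiaceae, which degrade mucin, Helicobacteraceae, segmented filamentous bacteria, which attach to the ileal epithelium, the facultative anaerobe families of the list (Enterobacteriaceae, Enterococcaceae, Streptococcaceae, Staphylococcaceae and Aerococcaceae), Tenericutes and Mollicutes under those names, non-target sequence such as plant plastids, and the reagent contaminant genera. A count of 0 allows a share of up to 0.00693% over all libraries and from 0.0768% to 0.446% in a single library. Acholeplasmataceae, bacteria without a cell wall that the deposited names place in Firmicutes, were found in 2 of 6 susceptible and 5 of 12 resistant mice.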

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

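The checks for single mice far from their group were set before the data were examined and covered the susceptible group, since the 12 resistant mice were too many for them. Of 47 measures checked, 10 had 1 of the 6 susceptible mice apart from the others by more than a gap test allows. Chance gives this in about 1 of 20 groups of continuous values. That rate does not hold for 7 of the 10, where the other 5 mice were at 0 counts and any count sets a mouse apart. Nor need it hold for Oscillospiraceae, where the mouse apart was itself at 0 counts. Its place was set by the 0.01 added to each percent before the log.

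Rikenellaceae, as a family and as a taxon group, made up 0.259% of counts in susceptible mouse 2 and from 3.14% to 13.0% in the other 5 susceptible mice. Oscillospiraceae had 0 counts in susceptible mouse 3 and made up 0.333% to 1.12% in the other 5. A count of 0 in that library allows a share of up to 0.171%, so the gap may be smaller than the test took it to be.

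The other 7 cases were taxa found in 1 susceptible mouse and at 0 counts in the other 5. Prevotellaceae made up 0.577% of counts in susceptible mouse 4. Susceptible mouse 2 held Deferribacteraceae at 0.185% and the butyrate-producing genera at 0.296%. Proteobacteria made up 0.102% of counts in susceptible mouse 6, and Muribaculaceae F-bfad3d and F-38b028 each 0.0256%, which is 1 count. Muribaculaceae F-df20a7 made up 0.155% in susceptible mouse 5.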

How the results depend on the processing

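The filter of 2 mice, the setting without the 2 libraries under 1500 counts and the sample number as a covariate were chosen after the results were seen, as was the check of which features were called without a filter. Of 100 drawn splits of the mice into 6 and 12, up to 4, 4 and 2 features, genera and families were called in another split, against 0 in the real one. Since any split gives at least 0 calls (100 of 100 at each level), this count says nothing about chance.

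Without a low-count filter edgeR called 64 features (62 higher and 2 lower in susceptible mice), 5 genera and 1 family, Desulfovibrionaceae. With a filter of 2 mice it called 10 features, 1 genus and 1 family. Single-mouse features may account for many of the 64, since 81.2% of them were found in 1 mouse against 58.2% of the table, but the filter of 2 mice kept 10 of the 64, so they do not account for all. Other divisions of the mice gave as many: 12 of 100 splits, the real one included, had at least 64 calls, up to 80 in another split, so chance is not excluded. No biological explanation beyond the response of the mice was tested.

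Limma on centred log-ratios called 1 genus, [Eubacterium]_xylanophilum_group, and the sample number as a covariate gave 1 genus and 1 family, in both cases Clostridia_vadinBB60_group. Leaving out 1 mouse in turn gave 0 to 1 features (1 without resistant mouse 7), 0 to 1 genera (1 without resistant mouse 1 or 3) and 0 to 1 families (1 without resistant mouse 1 or 12 or susceptible mouse 4 or 6). The difference in the Shannon index ran from 0.0313 (without susceptible mouse 6) to 0.191 (without susceptible mouse 2), in rarefied richness from -1.84 to 3.83, in the log2 ratio of Firmicutes to Bacteroidota from -0.0858 to 0.727 and in dispersion from -0.0181 to 0.0209. Without the 2 libraries under 1500 counts richness differed by -2.71 and log2 library totals by -0.22. Over all 18 mice, totals with no log differed by -38.3 counts. Resistant mouse 1 was the only resistant carrier of Clostridia_vadinBB60_group, and resistant mouse 7 of Muribaculaceae F-ab7f13, the taxa called without them. Resistant mouse 3 held 4 of the 6 resistant counts of Alistipes, the genus called without it. The cause of the other changes was not tested. Of 63 alternatives to the planned results other than single mice left out, 51 kept their direction and their side of the threshold.

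Directions turned for several taxa, none past the threshold before or after. On the percent scale the differences were -3.70 for Muribaculaceae, -0.0614 for Ruminococcaceae and Oscillospiraceae and -0.0244 for Deferribacteraceae, and Proteobacteria was 0.0156 as a log-ratio to the tested features. With DESeq2 size factors and with the DESeq2 test, the log2 fold change of Lachnospiraceae_NK4A136_group was -0.20 and -0.20, of the genus Muribaculaceae -0.85 and -0.85, of the family Lachnospiraceae -0.32 and -0.32, of the family Muribaculaceae -0.78 and -0.78 and of Oscillospiraceae -0.80 and -0.81. With limma these were -0.28 (genus Muribaculaceae), -0.18 (Lachnospiraceae), -0.26 (family Muribaculaceae) and -0.29 (Oscillospiraceae). With library totals alone they were -0.16 for the genus Muribaculaceae, -0.17 for the family and -0.28 for Oscillospiraceae. Without a filter the families Muribaculaceae and Oscillospiraceae were at -0.39 and -0.0264. With a filter of 2 mice the genus Muribaculaceae was at -0.15 and Lactobacillaceae at 0.40, and with a filter of 9 mice the genus was at -0.00732. Without the 2 low libraries it was at -0.42 and Lachnospiraceae_NK4A136_group at -0.00956, and with the sample number as a covariate Rikenellaceae_RC9_gut_group was at 0.0213.

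With single mice left out, log2 fold changes ran from 2.23 to 6.19 for the genus Clostridia_vadinBB60_group, 2.11 to 3.595 for [Eubacterium]_xylanophilum_group, 1.96 to 3.81 for Candidatus_Saccharimonas, 1.38 to 5.44 for Alistipes, 0.63 to 1.66 for the unnamed genera of Lachnospiraceae, 1.20 to 3.05 for those of Erysipelotrichaceae, 1.32 to 2.63 for [Eubacterium]_coprostanoligenes_group, 0.98 to 2.01 for GCA-900066575, -0.30 to 2.53 for Bacteroides, -0.37 to 1.63 for Lachnospiraceae_NK4A136_group, -0.67 to 0.40 for the genus Muribaculaceae, -1.26 to 0.0751 for Lachnospiraceae_UCG-001, -1.19 to 0.0348 for Lactobacillus and -1.55 to 0.0674 for Rikenellaceae_RC9_gut_group. Among families they ran from -0.37 to 2.08 for Lachnospiraceae, -0.42 to 0.48 for Muribaculaceae, -1.21 to -0.16 for Rikenellaceae, -0.71 to -0.00618 for Lactobacillaceae, -0.88 to 2.17 for Bacteroidaceae and -0.84 to 0.92 for Oscillospiraceae. The highest value of Clostridia_vadinBB60_group, 6.19, left out its only resistant carrier. Direction turned in up to 7 of 18 such runs for a named taxon, as for the genus Muribaculaceae and for Oscillospiraceae. Of 281 alternatives for the 30 named taxa other than single mice left out, 254 kept direction and side, 25 turned direction and 2 passed the threshold. Depth sets the limit for rare taxa: 0 counts allow a share of 0.0768% to 0.446% in a single mouse.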

Other observations

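Tests of the sample number, of genus presence and of features found together were chosen after the results were seen.

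Some features with the same genus-level name were found in exactly the same mice, more often than shuffled presence gives. Of the 84 features found in 4 to 14 mice, 11 pairs were found in identical sets of mice, against a mean of 0.074 and a highest value of 2 in 1000 shuffles of each feature's mice. The shuffles took mice as exchangeable. Richness differed between mice and neighbouring sample numbers were alike in composition, so the value expected by chance may be higher. All 11 pairs shared a genus-level name, which for Muribaculaceae is a family name, against 23.98% of all 3486 pairs. They included Lactobacillus F-40f7ad and F-8bbb51, found together in 8 mice at a median count ratio of 1.24, and Lachnospiraceae_NK4A136_group F-5d432e and F-c94d70, found together in 6 mice at a ratio of 1.28. The other 9 pairs were of Muribaculaceae features, 6 of them among the 4 features F-022bff, F-485590, F-b31949 and F-38b028 that shared 4 mice.

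Rarefied feature richness, but not genus richness, was higher in mice with higher sample numbers. The values argue against library depth, since the relation stood in richness rarefied to the lowest total (Spearman rho 0.851) and the total count did not follow the number (rho 0.0568, permutation p = 0.825). The response to peanut does not account for it either, since rho was 0.825 within the 12 resistant mice. Mice with neighbouring numbers were also more alike in composition (Mantel r 0.371, permutation p = 0.00055), which is consistent with a cage, litter, collection day or processing position shared by neighbours. Which of these it was stays open, because the labels used give none of them, and no biological explanation was tested.

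[Eubacterium]_xylanophilum_group was found in 6 of 6 susceptible and 2 of 12 resistant mice. Missed detection in shallow libraries is argued against for shares as high as those of the susceptible mice, if reads are taken as independent. Carriage at a lower share was not tested and may have been missed. At the lowest share in a susceptible mouse, 0.210 of the 10 resistant libraries without the genus would be expected to show 0 counts. That mouse carried the genus through the feature F-19eac7 alone. The other feature, F-b3e8c8, was found in 5 of 6 and 2 of 12 mice (Fisher's exact test, adjusted p = 0.608). Some genus reached a Fisher p as small in 0.986% of all 18564 splits of the mice. In the 3375 splits that kept 2 susceptible mice in each block of 6 consecutive numbers, the share was 1.30%. Such a p was thus rare among the 20 genera under shuffled groups. Presence per genus was chosen after the data were seen. These shares leave out the 84 features and 12 families also tested for presence, so chance is not excluded. Blocks of 6 numbers cannot separate direct neighbours, so a shared cage or litter is not excluded either. As a hypothesis found and tested on the same data, carriage of this genus may go with susceptibility. The margin is small, since with 1 mouse fewer, 5 of 5 against 2 of 12, the adjusted p was 0.0577 to 0.0679 (Fisher's exact test). Cages and litters were not given, and the abundance test in edgeR made no call of the genus (adjusted p = 0.366). For abundance, the adjusted p ran from 0.0054 to 0.891 over the alternatives on all 18 mice. With single mice left out it ran from 0.216 to 0.971 (edgeR).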
